A study of Danio rerio with 276 samples.

How the data were processed

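RNA was measured in single whole embryos at 5 days after fertilisation, 1 library per embryo, from 33 mutant lines in a background of mixed wild-type strains, per the labels. Libraries were stranded mRNA libraries made after poly(A) selection and sequenced as paired ends of 75 bp with a target of 25 M reads (M, 1e6), per the labels' protocols. Reads were aligned with STAR 2.5.2b-1 and counted per gene with featureCounts 1.6.0.1, and genotypes were compared with DESeq2 2.11.40.1, per the submitters' processing notes, which name no genome build and no order of steps.

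The values used here are read counts per gene that the authors had divided by 1 size factor per library before they were deposited. This normalised signal is the only per-library value in the deposited files. The authors' own comparison tables, as deposited, hold a mean count, a log2 fold change of mutant over wild type made with DESeq2, its standard error, and a p-value adjusted for multiple tests. Multiplying each column by a constant recovered whole numbers within 0.01 in 100% of the genes of every library used, which gave the reads per library. Each of 34 tables holds 32105 gene IDs, of which 26269 have a name and 4301 share that name with another ID. Symbols are printed as the name table gives them, and a shared name leaves the identity of the copy uncertain.

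Of 276 samples in the labels, 265 library columns were matched to a line and genotype by the column names. Another 4 columns, the wild types in the table of the second dnmt1 set, matched no sample of the labels and were not used. Tables of 7 lines (tbcb, npas4b, cmyb, dnmt1, rag1, pip5k1ba and atad5a) hold fewer columns than the labels list samples. Tables were normalised separately, so every test was made within a table. The table of the atad5a line was left out because its mutant and wild-type columns were alike (see the closing section). The second dnmt1 mutant set was therefore not refitted here, and its results are those of the authors' deposited table. That left 255 libraries in 32 lines, where 33 had been planned. Among genes with a mean of at least 100 reads over all libraries, no more than 1.34% had equal counts in any 2 libraries of different tables. Replicates are separate embryos, per the labels.

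The model, gene lists, line classes, rule for naming genes and most alternatives were chosen before the data were examined. Mutants and wild-type siblings of each line were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1) with a mean-variance trend, because the values are counts divided by size factors. Genes with a mean of at least 10 in the line were tested. Benjamini-Hochberg adjustment was made within each line, two-sided, with a threshold of 0.05 on the adjusted p. Fold changes are on the log2(value + 1) scale, and ± after them is the standard error of the fit unless an SD is named. After normalised reads, ± is the SD over the embryos of a group. After means over lines, it is the SD over lines. Counts of genes in a direction refer to mutant over wild type.

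The 38 gene lists were tested within lines with camera at a preset inter-gene correlation of 0.01, adjusted over all lines and lists together, for lists with at least 5 tested members, and again with an estimated correlation and with fry. Across lines, the mean log2 fold change of each list was tested with 100000 sign flips over lines, two-sided. Genes called in many lines were counted among those tested in at least 20 lines and set against 1000 permutations of gene names within each line, and 11 lines were taken as the limit. Lines were grouped into 8 classes by the known function of the mutated gene, and the correlation of log2 fold changes within and between classes was compared by permuting class labels 100000 times, one-sided. For calls on the chromosome of the mutated gene, chromosomes and gene order came from RefSeq genes of the GRCz12tu assembly matched by symbol. That test used genes with a mean of at least 50 and the 23 lines with at least 80% of genes and calls placed, limits set after the coverage and a first run over all lines had been seen.

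Genes were named by a rule of 6 parts. They are the mutated gene of each line, the 2 highest and 2 lowest called genes of each line with a proper gene name, non-overlapping groups and a mean of at least 50 in the higher group, the 12 genes higher and the 12 lower in the most lines, any gene of the T cell list, up to 4 members of another list, and up to 5 genes per direction shared by a class of at least 3 lines. Genes named outside the rule are marked as such. A list and 2 genes are not reported here, though the counts and adjustments include them.

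Alternatives were a pseudocount of 5, no expression filter, TMM factors (0.978 to 1.04) from edgeR 4.0.16, edgeR quasi-likelihood on the recovered reads, and leaving out each library. Summaries were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The comparisons were tested on simulated data with planted changes. With 4 mutants and 4 wild types (on the model of the lsm8 line), 1.49%, 29.2% and 92.1% of genes planted at log2 changes of 0.5, 1 and 2 were called. With 3 and 3 (rag1) the shares were 0%, 48.4% and 93.9%, and with 6 and 8 (pip5k1ba) 55.9%, 92.2% and 100%. At most 0.0632% of unchanged genes were called by limma, and a planted list was called in each case with 0 of 37 others. With 4 and 4 embryos, most changes of log2 0.5 were thus below detection. In the real libraries, splits other than by genotype called at most 7 genes in lsm8, 4 in rag1, 1111 in pip5k1ba and 1732 in anapc1. The median estimated inter-gene correlation was 0.26, and with estimated correlations 0 list calls passed, against 602 with the preset one. The simulated rates for unchanged genes and other lists therefore do not show how specific limma or camera was in these embryos.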

Results

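Single whole zebrafish embryos at 5 days after fertilisation were profiled by stranded poly(A) RNA sequencing. They came from lines found in a chemical (ENU) mutagenesis screen for loss of rag1 signal in the thymus, rag1 being the recombinase gene that marks developing T and B cells. Per the labels, embryos homozygous for the mutation were compared with homozygous wild-type siblings from crosses of carriers, and each library is 1 embryo. The labels list 276 samples in 33 lines, with a second mutant set for dnmt1. Of these, 265 library columns in 34 tables were matched to a genotype, and 255 libraries in 32 lines entered the comparisons, with 4 mutants and 4 wild types in most lines. Exceptions were pip5k1ba (6 mutants, 8 wild types), rag1 (3 and 3), tbcb and npas4b (4 and 3), cmyb (3 and 4) and dnmt1 (2 and 4). Depth was 4.48 to 262 M reads per library (median 27.9 M reads), and the il7r libraries were the deepest.

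The first question was whether each line carried a change in the mRNA of the gene it is named for. Among 29 lines whose gene matched a single tested ID, that mRNA fell in 8, rose in 5 and did not pass the test in 16. The largest decrease was in eif5, which encodes a translation initiation factor, with 24862 ± 7962 normalised reads in wild types and 3488 ± 79.6 in mutants (log2 fold change -2.79 ± 0.18, SE, n = 4 and 4). Other decreases were NEK7 (ENSDARG00000056966, -2.53 ± 0.19), TBCB (ENSDARG00000068404, -2.37 ± 0.21), SNAPC3 (ENSDARG00000101474, -1.87 ± 0.13), GEMIN5 (ENSDARG00000079257, -1.86 ± 0.12), TNPO3 (ENSDARG00000045680, -1.74 ± 0.20), PI4KA (ENSDARG00000076724, -1.64 ± 0.32) and UNC45A (ENSDARG00000103643, -1.15 ± 0.19). Of 2 IDs named MAT2A, the methionine adenosyltransferase that makes S-adenosylmethionine, ENSDARG00000040334 fell by 2.42 and ENSDARG00000037121 by 0.63 on the log2 scale in mat2aa mutants. The mRNA rose in mutants of lsm8 (2.83 ± 0.26), zbtb17 (2.29 ± 0.12), upf1 (1.15 ± 0.06), ikzf1 (0.92 ± 0.15) and cstf3 (0.57 ± 0.15). Of 9 IDs with a log2 fold change below 0 that did not pass, 3 had no overlap between mutants and wild types. They were NOL9 (-1.50 ± 0.23, adjusted p = 0.093), jak3 (-1.14 ± 0.24, adjusted p = 0.56) and RAG1 in its own line (-0.64 ± 0.19, adjusted p = 0.15). Of the IDs with a log2 fold change above 0 that did not pass, those without overlap were CCT5 (0.61 ± 0.20, adjusted p = 0.34), MCM10 (0.49 ± 0.20, adjusted p = 0.5) and POLE (0.40 ± 0.12, adjusted p = 0.081). With adjustment over the 33 IDs of mutated genes alone, 18 of these 29 lines passed. No named ID was matched to the spata5 gene, and neither NPAS4 ID passed in npas4b. The labels do not say how each mutation acts on the transcript, so an unchanged or higher level does not contradict a genotype.

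**Figure D1:**
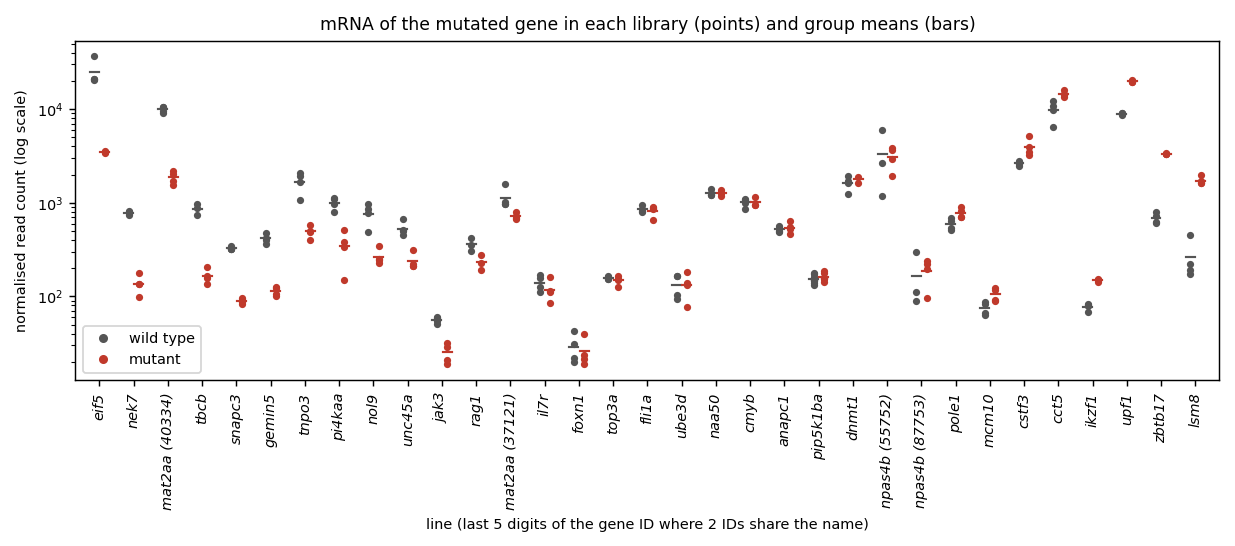
Normalised read count of the mutated gene on a log axis, 1 point per embryo, with group means as short bars, for 33 gene IDs in 31 lines ordered by log2 fold change. Mutants lie below wild types from eif5 to rag1 on the left and above them for upf1, zbtb17 and lsm8 on the right.

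T cell genes were lower in mutants across the lines. RAG1 (ENSDARG00000052122) was below the wild-type mean in all 32 lines and fell in 18, with a mean log2 fold change of -1.96 ± 0.97 (SD over 32 lines). The lowest was unc45a at -3.88 ± 0.36, where RAG1 had 248 ± 49.8 normalised reads in wild types and 17.3 ± 8.76 in mutants (n = 4 and 4), followed by ikzf1 at -3.58 ± 0.21. The chemokine receptor CCR9 (ENSDARG00000099738, 1 of 2 IDs of that name), which guides progenitors to the thymus, fell in 14 of 29 lines (mean -2.38 ± 1.42, SD) and the T cell kinase gene lck (ENSDARG00000102525) in 13 of 32 (-1.65 ± 0.75, SD). The other CCR9 ID (ENSDARG00000055186) did not always follow. It fell in ikzf1 (-2.59 ± 0.34) and mat2aa (-2.09 ± 0.29), but not in unc45a (0.14 ± 0.28) or snapc3 (-0.81 ± 0.34, adjusted p = 0.20). RAG2 (ENSDARG00000052121) fell in 7 lines, and ZAP70 (ENSDARG00000015752), the T cell receptor kinase, and rorc (ENSDARG00000087195) in 5 each. Not all members shared that direction: tnfrsf9a (ENSDARG00000060498) rose in 5 lines and fell in 0. Over 594 tests of list genes in 32 lines, 91 were lower and 14 higher with adjustment over all genes tested, against 173 lower and 19 higher adjusted over the list alone. At least 1 lower call was present in 20 lines, and in 27 when adjusted over the list alone. The mean log2 fold change of the list was below 0 in 32 of 32 lines, at -0.69 ± 0.37 (SD over lines). A two-sided sign-flip permutation test over lines gave p = 1e-05, the smallest that 100000 permutations can give (adjusted p = 0.00019 over 38 lists). Lines entered the screen through loss of thymic rag1 signal, so the direction of this list is not independent of how they were chosen. Within single lines camera called the list lower in 25, fry in 20, and camera with an estimated correlation in 0 (lowest adjusted p = 0.12 with an estimated correlation).

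**Figure D2:**
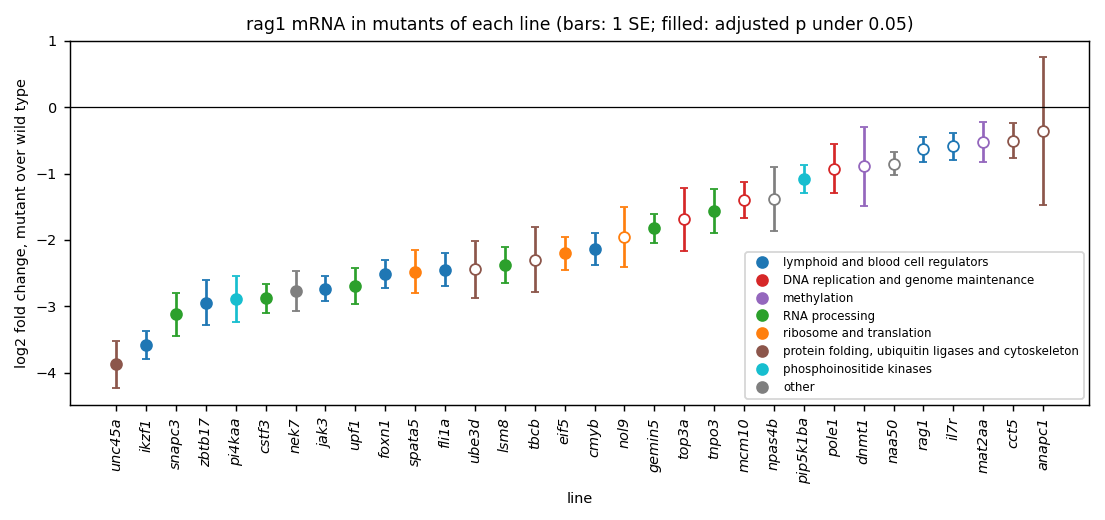
Log2 fold change of RAG1, mutant over wild type, on the y axis for 32 lines on the x axis, with bars of 1 SE and colours for the function of the mutated gene. All 32 points lie below 0, from -3.88 in unc45a to -0.36 in anapc1 (wild types 134.9 ± 148.7 normalised reads, SD), and the 18 filled points passed the test.

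The number of changed genes differed widely between lines. It exceeded 1000 in 12 lines, lay between 100 and 1000 in 5, and was under 100 in 15. Counts ran from 9755 in pi4kaa to 0 in top3a, among 20888 to 25690 genes tested per line. In top3a limma called 0 genes, edgeR called 0, and 737 had an unadjusted p under 0.05. Leaving out 1 library moved the count by over 1.5 times in 28 of 32 lines. The 4 lines that kept it were pi4kaa, mat2aa, pip5k1ba and cstf3. Of 136 such moves, 119 were to lower counts and 17 to higher. Smaller groups give fewer calls by themselves, so these moves do not by themselves show a dependence on single embryos. Which direction had more calls also turned over in at least 1 alternative fit in 14 lines. In the authors' deposited tables, made with other software, the adjusted p was under 0.05 for more genes in each of the 32 lines, from 16 in top3a to 10626 in pi4kaa. Genes given below as highest or lowest in a line are those with a gene name, no overlap between mutants and wild types, and a mean of at least 50 normalised reads in the higher group. For lists within lines, the members called, the mean log2 fold change and the camera adjusted p are given, and no list passed with an estimated correlation.

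**Figure D3:**
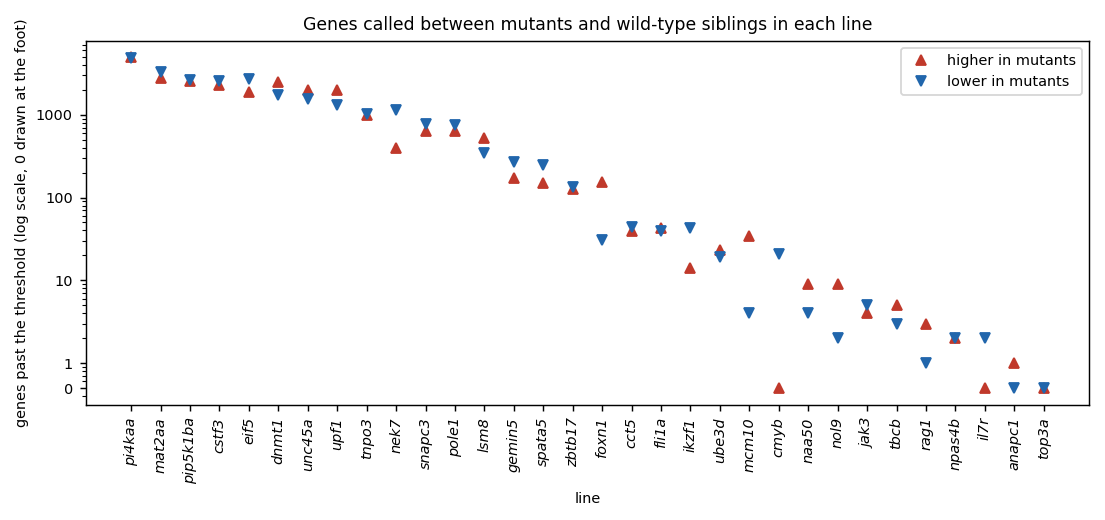
Number of genes higher (upward triangles) and lower (downward triangles) in mutants of each line, on a log axis with 0 drawn at the foot, for 32 lines in order of their total. The total falls from 9755 in pi4kaa to 0 in top3a, and cmyb has 21 lower and 0 higher.

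RAG1 fell in 6 of the 8 lines of lymphoid and blood cell regulators, and no gene of the T cell list passed in the other 2, rag1 and il7r. The ikzf1 line, mutant in the lymphoid transcription factor Ikaros, had 57 genes (14 higher, 43 lower), among them CCR9 (ENSDARG00000099738, 1 of 2 IDs of that name, -4.23 ± 0.40) and RAG1 (ENSDARG00000052122, -3.58 ± 0.21). The tryptophan pathway gene HAAO (ENSDARG00000076487, 3.14 ± 0.20) and the MHC class II chaperone gene cd74a (ENSDARG00000009087, 2.01 ± 0.30) rose. Lower by camera was the neutrophil list (0 higher, 2 lower of 18, mean -0.66, adjusted p = 5.6e-10, adjusted p = 0.12 with an estimated correlation). The cmyb line, mutant in a regulator of blood stem cells, had 21 genes (0 higher, 21 lower). The lysozyme gene lyz, a neutrophil and macrophage marker, had 605 ± 143 normalised reads in wild types and 7.01 ± 2.61 in mutants (ENSDARG00000057789, -6.27 ± 0.30, n = 4 and 3), and hdac7b (ENSDARG00000073850, -3.77 ± 0.33) also fell. Lower by camera in cmyb was the erythroid list (0 higher, 1 lower of 21, mean -1.70, adjusted p = 7.5e-19, adjusted p = 0.18 with an estimated correlation). The fall was not particular to blood genes, as the means of the exocrine pancreas (-2.15) and lens (-2.05) lists were lower still. Mutants of zbtb17, which encodes the zinc finger factor Miz-1, had 261 genes (126 higher, 135 lower). CNPY4 (ENSDARG00000055797, -6.58 ± 0.50) and the lipid transfer gene scp2b (ENSDARG00000102356, -5.69 ± 0.20) were lowest. The ATP-gated channel gene P2RX4 (ENSDARG00000042452, 1 of 2 IDs of that name, 4.53 ± 0.29) was higher. The fli1a line, mutant in an endothelial transcription factor, had 82 genes (43 higher, 39 lower). Among them were the natriuretic peptide gene nppb (ENSDARG00000052958, 3.61 ± 0.65), the complement gene c3a.2 (ENSDARG00000087359, 3.06 ± 0.14), RAG1 (ENSDARG00000052122, -2.45 ± 0.25) and the cone opsin gene opn1mw2 (ENSDARG00000044280, -2.03 ± 0.29). In foxn1, the thymic epithelium transcription factor, 186 genes (155 higher, 31 lower) changed. There nlrc11 (ENSDARG00000068621) had 0.198 ± 0.395 normalised reads in wild types and 357 ± 121 in mutants. The nitric oxide synthase gene NOS2 (ENSDARG00000026925, 1 of 2 IDs of that name, 4.49 ± 0.53) rose, and odam (ENSDARG00000074476, -4.15 ± 0.79) and fut9d (ENSDARG00000028098, -2.90 ± 0.27) fell. The jak3 line, mutant in the kinase of the common gamma chain cytokine receptors, had 9 genes (4 higher, 5 lower). They include RAG1 (ENSDARG00000052122, -2.73 ± 0.18), znfl1l (ENSDARG00000094197, -4.50 ± 0.55), the properdin gene cfp (ENSDARG00000094451, 2.02 ± 0.15) and STAP2 (ENSDARG00000043281, 1.85 ± 0.25). In the rag1 line 4 genes (3 higher, 1 lower) passed. Of these, tgm1l3 (ENSDARG00000005913, 5.24 ± 0.35) and serpinb1l4 (ENSDARG00000096888, 3.59 ± 0.33) have names. RAG1 itself was not among them. The il7r line, mutant in the interleukin 7 receptor, had 2 genes (0 higher, 2 lower). They were si:dkeyp-28d2.4 (ENSDARG00000041828, -2.50 ± 0.17) and si:ch211-69l10.4 (ENSDARG00000098036, -1.48 ± 0.15). These are named here because the count was small and were chosen after their values were seen. Leaving out wild-type library 1 moved the il7r count to 20 (15 higher, 5 lower) and the rag1 count to 16.

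Among lines with a mutation in a DNA replication gene, mcm10 and pole1 shared a set of higher genes, whose values in top3a were above 0 and did not pass. Mutants of mcm10, a replication initiation factor, had 38 genes (34 higher, 4 lower), and mutants of pole1, the leading strand DNA polymerase, had 1374 genes (629 higher, 745 lower). The genes called higher in both were led by si:dkey-204l11.1 (ENSDARG00000079403, mean 4.75 ± 1.03, SD over the 3 lines of the class), bmb (ENSDARG00000096603, 2.94 ± 0.41), RNF14 (ENSDARG00000078683, 1 of 3 IDs of that name, 2.23 ± 0.73), the ubiquitin ligase gene mdm2 (ENSDARG00000033443, 1.95 ± 0.74) and the ribosomal protein-like gene rps27l (ENSDARG00000100513, 1.84 ± 0.84). In top3a none of these passed (adjusted p = 0.89), with log2 fold changes of 3.57 ± 0.91, 2.53 ± 0.73, 1.46 ± 0.40, 1.096 ± 0.40 and 0.91 ± 0.44 in the same order (SE). These higher genes were not particular to the class. Over all lines bmb rose in 19, RNF14, mdm2 and rps27l in 18 each, and si:dkey-204l11.1 in 17 of 27 tested. The cerebellin family gene cbln12 (ENSDARG00000068232) was lower in both mcm10 and pole1. Higher in mcm10 was the DNA replication list (0 higher, 0 lower of 54, mean 0.50, adjusted p = 4.7e-30, adjusted p = 0.26 with an estimated correlation). In pole1 the NLR family gene nlrc3l2 (ENSDARG00000089304, 4.31 ± 0.89) was high, and CRTAC1 (ENSDARG00000059826, 1 of 2 IDs of that name, -2.32 ± 0.23) fell. Mutants of top3a, a topoisomerase gene, had no called gene, yet their T cell and thymocyte list (0 higher, 0 lower of 20, mean -0.87, adjusted p = 2.5e-08, adjusted p = 0.43 with an estimated correlation) was lower. Lower too was their DNA replication list (0 higher, 0 lower of 55, mean -0.40, adjusted p = 1.1e-15, adjusted p = 0.61 with an estimated correlation). The genotype split of top3a called 0 genes and another split 2, so its lists may reflect differences between embryos regardless of genotype. The pole1 count was 557 without mutant library 5, and the mcm10 count 16 without wild-type library 3.

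The 2 lines of methylation enzymes differed. In mat2aa 6022 genes (2740 higher, 3282 lower) changed. Photoreceptor genes fell, the photoreceptor list (1 higher, 30 lower of 33, mean -2.04, adjusted p = 6.2e-18, adjusted p = 0.5 with an estimated correlation). Neuron genes did too, the neuron list (0 higher, 23 lower of 26, mean -1.32, adjusted p = 9.4e-17, adjusted p = 0.49 with an estimated correlation). The lowest genes were the relaxin gene rln3a (ENSDARG00000070780, -5.67 ± 0.34) and rp1l1b (ENSDARG00000088377, -5.44 ± 0.39). The highest were the globin gene hbaa1 (ENSDARG00000097011), with 0.996 ± 1.39 normalised reads in wild types and 68.8 ± 23.1 in mutants, and the complement gene c3a.5 (ENSDARG00000053462, 5.30 ± 0.54). In dnmt1, the maintenance DNA methyltransferase, 4231 genes (2486 higher, 1745 lower) passed with 2 mutants and 4 wild types. Ribosomal protein genes rose, the cytosolic ribosomal proteins list (70 higher, 0 lower of 76, mean 0.86, adjusted p = 1.7e-21, adjusted p = 0.67 with an estimated correlation). List means in dnmt1 ran from -0.31 (circadian clock) to 0.99 (exocrine pancreas), with liver at 0.78, so the rise was not particular to ribosomal protein genes. The dnmt1 count fell to 2 without wild-type library 1, 3 without wild-type library 3 and 1 without mutant library 6, which leaves 1 mutant. In the second dnmt1 mutant set, the authors' deposited table had 146 genes at an adjusted p under 0.05 (68 higher, 78 lower). The authors' deposited table gave log2 fold changes of 2.01 (SE 0.14) for cfap70 (ENSDARG00000058508), a cilium gene, 1.01 (SE 0.15) for cyp2k21 (ENSDARG00000105151), -1.58 (SE 0.15) for the embryonic globin gene hbae1.1 (ENSDARG00000089475) and -1.27 (SE 0.15) for RAG1. For RAG1 in the first set, the authors' deposited table gave -0.66 (adjusted p = 0.14). Across 21151 genes the log2 fold changes of the sets in the authors' deposited tables correlated at r = 0.21, over genes that are not independent replicates. Higher calls shared by both sets in the authors' deposited tables numbered 21 where 9.4 would be shared by independent lists, and lower calls 12 where 7.25 would be.

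RNA processing lines had from 438 to 4829 changed genes. Mutants of lsm8, a subunit of the ring bound to U6 RNA in the spliceosome, had 877 genes (528 higher, 349 lower). Higher by camera was the spliceosome list (38 higher, 0 lower of 77, mean 0.88, adjusted p = 2.9e-30, adjusted p = 0.17 with an estimated correlation). Their highest genes were bmb (ENSDARG00000096603, 4.29 ± 0.17) and brf2 (ENSDARG00000002060, 3.91 ± 0.19), an RNA polymerase III factor. Lowest were cd74a (ENSDARG00000009087, -3.49 ± 0.57) and the pancreatic granule gene SYCN (ENSDARG00000090899, 1 of 2 IDs of that name, -3.21 ± 0.53). In tnpo3, the importin of splicing factors, 2010 genes (979 higher, 1031 lower) changed. Digestive enzyme genes fell, the exocrine pancreas list (0 higher, 19 lower of 24, mean -1.75, adjusted p = 1.1e-21, adjusted p = 0.42 with an estimated correlation). Lowest was the elastase gene cela1.3 (ENSDARG00000043173, -4.94 ± 0.41), then lyz (ENSDARG00000057789, -3.79 ± 0.34). Its highest genes were lrrc66 (ENSDARG00000093370, 3.65 ± 0.31) and the intelectin gene ITLN1 (ENSDARG00000095082, 1 of 2 IDs of that name, 3.25 ± 0.22). The upf1 line, mutant in the helicase of nonsense-mediated mRNA decay, had 3328 genes (2002 higher, 1326 lower). Genes of that pathway rose, the nonsense-mediated decay factors list (8 higher, 0 lower of 14, mean 0.49, adjusted p = 3.4e-06, adjusted p = 0.23 with an estimated correlation). Also higher was the ATF4 and amino acid response list (22 higher, 0 lower of 35, mean 0.75, adjusted p = 2.7e-13, adjusted p = 0.22 with an estimated correlation). The long noncoding RNA gene lnc.85 (ENSDARG00000105273) had 403 ± 77.4 normalised reads in wild types and 14917 ± 1254 in mutants, and jac9 (5.93 ± 0.67) rose too. The hemopexin gene hpxa (ENSDARG00000012609, -5.29 ± 0.56) and cela1.5 (ENSDARG00000043168, -3.95 ± 0.89) fell. In cstf3, an mRNA cleavage factor, 4829 genes (2265 higher, 2564 lower) changed. sla2a (ENSDARG00000099887, 5.83 ± 0.71) was highest and the astacin protease genes c6ast3 (ENSDARG00000024503, -6.32 ± 0.69) and c6ast4 (ENSDARG00000052578, -6.26 ± 0.78) were lowest. Higher there was the interferon response list (9 higher, 0 lower of 23, mean 1.17, adjusted p = 1.8e-06, adjusted p = 0.58 with an estimated correlation). Mutants of gemin5, which binds small nuclear RNAs for the SMN complex, had 438 genes (171 higher, 267 lower). The retinal factor gene atoh7 (ENSDARG00000069552, -4.68 ± 0.42) and CCDC90B (ENSDARG00000044626, -5.02 ± 0.48) were lowest. The complement gene bfb (ENSDARG00000005616, 4.58 ± 0.97) and the sialidase gene NEU3 (ENSDARG00000010047, 1 of 4 IDs of that name, 4.47 ± 0.92) were highest. Lower was the mitosis list (0 higher, 9 lower of 41, mean -0.82, adjusted p = 2.1e-25, adjusted p = 0.5 with an estimated correlation). In snapc3, a factor for small nuclear RNA transcription, 1408 genes (641 higher, 767 lower) changed. jac9 (ENSDARG00000074983, 6.59 ± 0.42) and jac8 (ENSDARG00000076958, 5.85 ± 0.53) were highest. The pancreatic lipase gene CEL (ENSDARG00000017490, 1 of 2 IDs of that name, -4.17 ± 0.62) and the carboxypeptidase gene CPA1 (ENSDARG00000030915, 1 of 2 IDs of that name, -3.97 ± 0.46) were lowest. Higher there too was the spliceosome list (24 higher, 0 lower of 76, mean 0.40, adjusted p = 1.8e-09, adjusted p = 0.61 with an estimated correlation). Over the 6 lines bmb was higher in all 6 (mean 2.98 ± 0.83, SD) and si:dkey-14d8.7 (ENSDARG00000045834) lower in all 6 (-3.13 ± 0.52). Neither change was particular to this class. Over all 32 lines bmb rose in 19, and si:dkey-14d8.7 fell in 13 and rose in 2. The gemin5 count was 1143 without mutant library 7 and 81 without wild-type library 2.

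Digestive enzyme genes fell in eif5 and spata5, and in nol9 their list mean was lower with no member called. This was not particular to these lines, as camera called the exocrine pancreas list lower in 22 of all 32 lines. Mutants of eif5 had 4547 genes (1868 higher, 2679 lower). Lens genes fell, the lens list (0 higher, 25 lower of 26, mean -4.10, adjusted p = 3.3e-21, adjusted p = 0.42 with an estimated correlation). Lowest were the crystallin genes CRYAA (ENSDARG00000053502, -7.83 ± 0.58) and CRYBB1 (ENSDARG00000068507, -7.33 ± 1.35). Lower as well was the exocrine pancreas list (0 higher, 23 lower of 25, mean -3.50, adjusted p = 4.4e-21, adjusted p = 0.43 with an estimated correlation). Amino acid response genes rose, the ATF4 and amino acid response list (25 higher, 1 lower of 35, mean 1.25, adjusted p = 8.1e-14, adjusted p = 0.16 with an estimated correlation). Highest were the ubiquitin-like interferon-induced gene isg15 (ENSDARG00000086374, 5.47 ± 0.32) and igfn1.2 (ENSDARG00000075926, 5.11 ± 0.44). Mutants of spata5, an ATPase of ribosome maturation, had 397 genes (151 higher, 246 lower). The pancreatic genes SYCN (ENSDARG00000103687, 1 of 2 IDs of that name, -5.77 ± 0.69) and the amylase gene amy2a (ENSDARG00000013856, -5.43 ± 0.78) were lowest. bmb (ENSDARG00000096603, 3.15 ± 0.38) and isg15 (ENSDARG00000086374, 2.19 ± 0.32) were highest. Higher too was the ribosome biogenesis list (15 higher, 0 lower of 66, mean 0.56, adjusted p = 3e-30, adjusted p = 0.5 with an estimated correlation), and lower the exocrine pancreas list (0 higher, 18 lower of 24, mean -3.69, adjusted p = 1.8e-26, adjusted p = 0.47 with an estimated correlation). In nol9, a kinase of ribosomal RNA processing, 11 genes (9 higher, 2 lower) changed. They include bmb (ENSDARG00000096603, 3.52 ± 0.33), RNF14 (ENSDARG00000078683, 1 of 3 IDs of that name, 2.94 ± 0.33), the lens galectin gene GRIFIN (ENSDARG00000033382, -4.37 ± 0.38) and c3a.3 (ENSDARG00000052207, -1.78 ± 0.22). Lower in nol9 was the exocrine pancreas list (0 higher, 0 lower of 25, mean -1.80, adjusted p = 1.2e-11, adjusted p = 0.6 with an estimated correlation). The ribosome biogenesis list (0 higher, 0 lower of 66, mean 0.38, adjusted p = 5.3e-18, adjusted p = 0.52 with an estimated correlation) was higher. The nol9 count was 76 without wild-type library 1 (15 higher, 61 lower), and the eif5 count was 9077 without wild-type library 4 and 2167 without mutant library 7.

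The heat shock list was called higher by camera in 4 of 5 lines of protein folding factors, ubiquitin ligases and cytoskeleton genes, and in none with an estimated correlation (values below). It was called higher by camera in 17 of all 32 lines, and its mean of 0.61 in this class against 0.20 in the other lines did not pass (adjusted p = 0.61). In cct5, a subunit of the chaperonin that folds actin and tubulin, 83 genes (39 higher, 44 lower) changed. The heat shock gene hspa1b (ENSDARG00000056210) had 50.5 ± 11.2 normalised reads in wild types and 1363 ± 1122 in mutants. The actin gene ACTC1 (ENSDARG00000057911, 3.78 ± 0.33) rose, and the phosphatase gene alp3 (ENSDARG00000098063, -3.68 ± 0.64) and GRIFIN (ENSDARG00000033382, -3.65 ± 0.64) fell. The cytosolic heat shock response list (9 higher, 0 lower of 31, mean 1.15, adjusted p = 1.8e-22, adjusted p = 0.18 with an estimated correlation) was higher. Lower was the lens list (0 higher, 1 lower of 26, mean -3.15, adjusted p = 8.9e-26, adjusted p = 0.48 with an estimated correlation). In tbcb, a tubulin folding cofactor, 8 genes (5 higher, 3 lower) changed. They include hsp70.1 (ENSDARG00000029688, 3.14 ± 0.40), HSP90AA1 (ENSDARG00000024746, 2.59 ± 0.17), the retinal transcription factor gene FOXN4 (ENSDARG00000010591, -2.25 ± 0.27) and TBCB itself. The cytosolic heat shock response list (3 higher, 0 lower of 31, mean 1.01, adjusted p = 2.6e-21, adjusted p = 0.26 with an estimated correlation) was higher. Higher too was the tubulins list (0 higher, 0 lower of 19, mean 0.85, adjusted p = 1.1e-16, adjusted p = 0.32 with an estimated correlation). Mutants of unc45a, a myosin chaperone, had 3522 genes (1993 higher, 1529 lower). scpp8 (ENSDARG00000093124, 6.23 ± 0.89) and the leptin gene lepa (ENSDARG00000091085, 5.63 ± 0.45) were highest. gig2l (ENSDARG00000091730, -6.99 ± 0.53) and the immunoproteasome gene psmb13a (ENSDARG00000001656, -5.95 ± 0.77) were lowest. The interferon response list (0 higher, 16 lower of 28, mean -1.93, adjusted p = 1.4e-09, adjusted p = 0.49 with an estimated correlation) fell. Higher were the inflammation list (17 higher, 1 lower of 28, mean 1.35, adjusted p = 9.6e-09, adjusted p = 0.42 with an estimated correlation) and the cytosolic heat shock response list (14 higher, 1 lower of 31, mean 0.83, adjusted p = 8.5e-06, adjusted p = 0.5 with an estimated correlation). In ube3d, a ubiquitin ligase, 42 genes (23 higher, 19 lower) changed. The fatty acid binding gene fabp1b.2 (ENSDARG00000103398, 3.70 ± 0.36) and dnaaf19 (ENSDARG00000053455, 3.52 ± 0.28), an axonemal dynein assembly factor, were highest. pm20d1.1 (ENSDARG00000037551, -2.57 ± 0.24) and the crystallin gene crygm2d18 (ENSDARG00000073750, -2.19 ± 0.35) were lowest. Higher was the cytosolic heat shock response list (0 higher, 0 lower of 31, mean 0.31, adjusted p = 2.3e-05, adjusted p = 0.17 with an estimated correlation). In anapc1, a subunit of the anaphase promoting complex, 1 gene passed, the mitochondrial transcript mt-atp8 (ENSDARG00000063910, 2.36 ± 0.18). Higher was its exocrine pancreas list (0 higher, 0 lower of 24, mean 2.07, adjusted p = 0.0021, adjusted p = 0.82 with an estimated correlation). So was its lens list (0 higher, 0 lower of 26, mean 1.77, adjusted p = 0.0017, adjusted p = 0.82 with an estimated correlation). Its cytosolic heat shock response list (0 higher, 0 lower of 31, mean -0.25, adjusted p = 0.21, adjusted p = 0.91 with an estimated correlation) did not pass. Another split of the anapc1 libraries called 1732 genes, so its lists may reflect differences between embryos regardless of genotype. The hsp70.1 gene was higher in cct5, tbcb and unc45a (ENSDARG00000029688, 3 of 5 lines) and the cytochrome gene cyp2n13 (ENSDARG00000042953) lower in cct5, unc45a and ube3d (mean -1.59 ± 2.32, SD over 5 lines). The cct5 count was 209 without wild-type library 1 and 21 without wild-type library 3, and the anapc1 gene was lost without any of 5 libraries.

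The phosphoinositide kinase lines were among the 4 lines with the most changed genes. The pip5k1ba count came from 8 wild types and 6 mutants, and larger groups detect smaller changes. Its rank is therefore not comparable with lines of 4 and 4. Another split of the pip5k1ba libraries called 1111 genes. In pi4kaa, the kinase that supplies phosphatidylinositol 4-phosphate at the plasma membrane, 9755 genes (4942 higher, 4813 lower) changed. Photoreceptor genes fell, the photoreceptor list (0 higher, 32 lower of 33, mean -4.48, adjusted p = 1.8e-24, adjusted p = 0.42 with an estimated correlation). The retinal gene rp1l1b (ENSDARG00000088377, -7.67 ± 0.37) and gvin1l2 (ENSDARG00000102364, -7.65 ± 1.00) were lowest. Neutrophil genes rose, the neutrophil list (15 higher, 0 lower of 20, mean 2.31, adjusted p = 1.2e-07, adjusted p = 0.5 with an estimated correlation). Inflammation genes rose with them, 24 of 29 members higher and 1 lower (camera adjusted p = 4.2e-09, adjusted p = 0.6 with an estimated correlation). The leptin gene lepb (ENSDARG00000045548) had 3.92 ± 2.69 normalised reads in wild types and 3877 ± 1743 in mutants, and the collagenase gene mmp13a (ENSDARG00000012395, 6.73 ± 0.47) rose. In pip5k1ba, which makes phosphatidylinositol 4,5-bisphosphate, 5116 genes (2521 higher, 2595 lower) changed. jac9 (ENSDARG00000074983, 6.64 ± 0.66) and spata6l (ENSDARG00000004874, 6.14 ± 0.22) were highest. The chymotrypsinogen gene ctrb.3 (ENSDARG00000039730, -4.69 ± 0.28) and CEL (ENSDARG00000029822, 1 of 2 IDs of that name, -4.48 ± 0.41) were lowest. Lower as a group was the exocrine pancreas list (0 higher, 23 lower of 24, mean -3.43, adjusted p = 3e-30, adjusted p = 0.24 with an estimated correlation). The kinase gene itself did not pass in pip5k1ba (0.08 ± 0.09, adjusted p = 0.54, n = 8 and 6).

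Of the remaining lines, nek7 lost digestive enzyme transcripts most. In this mutant of a mitotic kinase, 1547 genes (395 higher, 1152 lower) changed. The astacin gene c6ast4 (ENSDARG00000052578) had 21825 ± 6189 normalised reads in wild types and 32.3 ± 28.4 in mutants and the trypsin gene prss59.1 (ENSDARG00000079274) 58993 ± 21100.2 normalised reads in wild types and 109 ± 24.3 in mutants (n = 4 and 4). The exocrine pancreas list (0 higher, 24 lower of 24, mean -6.34, adjusted p = 1.7e-54, adjusted p = 0.18 with an estimated correlation) fell as a whole. Lower too was the lens list (0 higher, 23 lower of 26, mean -3.07, adjusted p = 1.2e-29, adjusted p = 0.26 with an estimated correlation). The intestine list (0 higher, 19 lower of 27, mean -2.30, adjusted p = 5.5e-19, adjusted p = 0.25 with an estimated correlation) fell as well. Highest were PLAC8 (ENSDARG00000094438, 1 of 2 IDs of that name, 4.97 ± 0.40) and the interferon-induced gene ifi44f5 (ENSDARG00000094747), which had 0 reads in all 4 wild types and a mean of 50.7 ± 19.1 in mutants. In naa50, an N-terminal acetyltransferase, 13 genes (9 higher, 4 lower) changed. isg15 (ENSDARG00000086374, 2.46 ± 0.25) and bmb (ENSDARG00000096603, 2.33 ± 0.15) were highest and the complement gene c3a.3 (ENSDARG00000052207, -0.76 ± 0.09) was lowest. In npas4b, a neuronal transcription factor, 4 genes (2 higher, 2 lower) passed. They were the potassium channel gene KCNJ10 (ENSDARG00000105022, 1 of 2 IDs of that name, 2.03 ± 0.22), the defensin gene defbl1 (ENSDARG00000075161, -3.40 ± 0.34), the mitochondrial gene CHCHD10 (ENSDARG00000010717, -1.83 ± 0.14) and zgc:165423 (ENSDARG00000052905, 1.33 ± 0.15), the last named after its value was seen. The npas4b count was 412 without wild-type library 1 and 0 without wild-type library 3, mutant library 6 or mutant library 7.

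Some genes changed in many lines with different mutated genes. Among 21813 genes tested in at least 20 lines, 16 rose and 28 fell in at least 11 of the 32 lines. Shuffling gene names within each line gave 0 such genes in each of 1000 permutations, where the most lines reached by any gene was 8. The shuffle treats all genes of a line as equally easy to call, so it does not allow for genes that pass more readily in any line. Those that rose include mdm2 in 18 lines (mean 0.96 ± 0.85, SD over lines), rps27l in 18 (1.01 ± 0.85), the cyclin gene CCNG1 (ENSDARG00000076667) in 16 (0.69 ± 0.57) and PHLDA3 (ENSDARG00000037804) in 15 (0.84 ± 0.69). The most widespread rise was bmb, which is needed for nuclear fusion in the early embryo, in 19 lines (1.87 ± 1.48), with RNF14 in 18 and si:dkey-204l11.1 in 17 of 27. The interferon-induced genes isg15 (ENSDARG00000086374) and isg20 (ENSDARG00000079783) rose in 13 each, the apoptosis gene casp8 (ENSDARG00000058325) in 13 and the collagen chaperone gene SERPINH1 (ENSDARG00000019949, 1 of 2 IDs of that name) in 12. None of these fell in any line. Among genes that fell, RAG1 (18 lines), CCR9 (14) and lck (13) led. Retinal and neural progenitor genes followed, namely sox12 (ENSDARG00000025847) and OTX2 (ENSDARG00000011235) in 13 each and higher in 1 each, atoh7 (ENSDARG00000069552) in 12 (mean -1.54 ± 1.64) and NEUROD1 (ENSDARG00000019566) in 12 (-0.44 ± 0.40). The bile salt lipase gene CEL (ENSDARG00000017490, 1 of 2 IDs of that name) fell in 12 and rose in 2, the cytochrome genes cyp3c4 (ENSDARG00000070021) and cyp2n13 fell in 13 and 12, si:dkey-14d8.7 fell in 13 and rose in 2, and si:dkey-14d8.6 (ENSDARG00000045835) fell in 12 of 31.

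Several tissue and stress gene lists moved in the same direction across lines. Besides the T cell list, lists of several tissues and stress responses had a mean that differed from 0 over 32 lines in the sign-flip permutation test. The exocrine pancreas list was lower in 27 lines (mean log2 fold change -1.26 ± 1.66, SD over lines, adjusted p = 0.00066), from -6.34 in nek7 to 2.07 in anapc1 (a line whose embryos differed widely regardless of genotype), and its members were called lower 204 times and higher 19 times. Lens (-0.76 ± 1.29, adjusted p = 0.0067), photoreceptor (-0.45 ± 0.88, adjusted p = 0.00076), intestine (-0.42 ± 0.62, adjusted p = 0.0013), neural progenitor and ciliary margin (-0.29 ± 0.37, adjusted p = 0.00066) and erythroid lists (-0.22 ± 0.40, adjusted p = 0.0082) were lower. Inflammation (0.33 ± 0.53, adjusted p = 0.0012), cytosolic heat shock (0.26 ± 0.39, adjusted p = 0.0012), germline and meiosis (0.17 ± 0.23, adjusted p = 0.0013) and spliceosome lists (0.10 ± 0.22, adjusted p = 0.026) were higher. The germline list had only 16 higher and 8 lower calls of its members over all lines. The ATF4 list did not pass (0.13 ± 0.32, adjusted p = 0.058), nor did the neutrophil (-0.03 ± 0.55, adjusted p = 0.83) and macrophage lists (-0.07 ± 0.42, adjusted p = 0.46). Within lines camera called 602 of 1216 pairs of line and list (279 up, 323 down), fry 169, and camera with an estimated correlation 0, with a lowest adjusted p = 0.12 with an estimated correlation, 121 pairs at an unadjusted p under 0.05 and a median estimated correlation of 0.26.

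**Figure D4:**
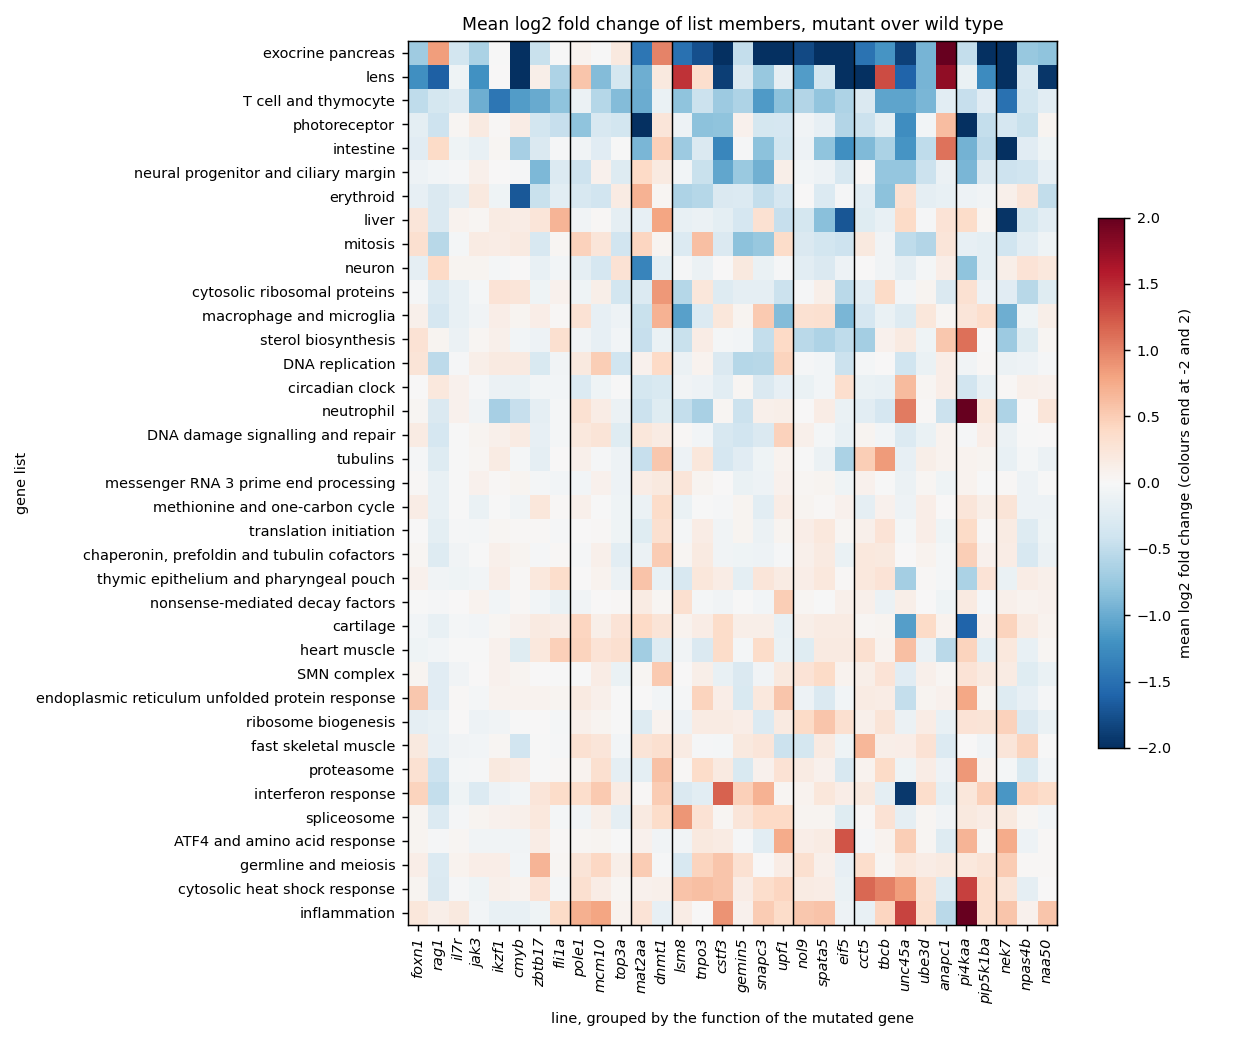
Mean log2 fold change of the members of 37 gene lists (rows, ordered by their mean over lines) in 32 lines (columns, grouped by the function of the mutated gene, black lines between groups), with colours ending at -2 and 2. The exocrine pancreas, lens and T cell rows at the top are mostly blue, and the inflammation and heat shock rows at the foot mostly red.

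Lines of 1 class were not detectably more alike than lines of different classes. The correlation of log2 fold changes over 19755 genes, which are not independent replicates, averaged 0.09 ± 0.18 (SD) over 64 pairs of lines in the same class and 0.10 ± 0.18 over 432 pairs in different classes. The one-sided permutation test of class labels gave p = 0.70. The most alike pair was pi4kaa and unc45a (r = 0.64), whose genes are in different classes, followed by spata5 and nek7 (0.59), nek7 and eif5 (0.56), and npas4b and rag1 (0.53). The npas4b and rag1 lines had 4 called genes each, and 6 of 35 and 2 of 10 splits of their libraries gave at least as many. Their likeness may thus reflect differences between embryos regardless of genotype. The most opposed were nek7 and anapc1 (-0.50), with the same reservation for anapc1. Mean list values in the lines of a class against all other lines were compared in 190 exact permutation tests, two-sided, and 0 passed after adjustment (9 at an unadjusted p under 0.05). Closest was the spliceosome list in RNA processing lines, at 0.38 against 0.04 in the others (adjusted p = 0.075). The ribosome biogenesis list was at 0.42 in the ribosome and translation lines against 0.02 in the others (adjusted p = 0.12).

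Calls were more frequent on the chromosome that carries the mutated gene. In 23 lines where at least 80% of the tested genes and of the calls could be placed, 10.1% of genes on that chromosome were called against 7.92% elsewhere, 672 higher and 603 lower. The pooled odds ratio was 1.39 (95% confidence interval 1.304 to 1.49). Fisher exact tests passed in 13 of the 23 lines, all above 1, with the highest in ikzf1 (odds ratio 16.7, adjusted p = 2.8e-09), where 13 of 32 called genes lay on it. Within the chromosome, the 200 genes on each side of the mutated gene were called more often than genes farther away, 12.1% against 9.21% (odds ratio 1.62, 1.41 to 1.86). The calls of the other lines on the same chromosomes gave a geometric mean odds ratio of 0.934 over the 23 lines (range 0.666 to 1.39).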

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

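Of the tests in this part, the 3 trends over lines for the T cell list and the neighbour and other-line tests for the chromosome were written before they were run. The other 3 tests of the T cell list were chosen after those trends were seen, and the test of the atad5a columns after the likeness was seen. The test on the share of abundant genes replaced one against the median of all genes (list mean less median -0.688), which decides nothing because size factors hold that median near 0 (-0.032 to 0.045).

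The lower T cell list in all 32 lines was weighed against 3 explanations: a wide change of the embryo, depth, and a few abundant genes. Their trends over lines were weak and decided nothing. The Spearman correlation was -0.0588 with the number of called genes, -0.0982 with the depth ratio and -0.233 with the share of the 10 most abundant genes. A wide change of the embryo was left open: in a regression on the number of calls the list mean at 0 calls was -0.634 (-0.918 to -0.391), but leaving out 1 library moved that number by over 1.5 times in 28 of 32 lines, so it is a poor measure of such a change. The list mean was -0.762 in the 13 lines whose mutants were deeper, 13 of 13 below 0 (sign-flip permutation p = 0.00029), against shallower mutants in those lines. Since 32 of 32 lines were already known to lie below 0, the signs were fixed in advance. The sign-flip p-values of this test and of the next therefore add no support. For a few abundant genes taking the counts, the change in the share of the 10 most abundant genes was used. In reads scaled by library totals it would shift all others by -0.041 to 0.031 on the log2 scale. The list mean less that shift was -0.677, below 0 in 32 of 32 lines (sign-flip permutation p = 0.00001). Size factors already take out a shift common to all genes, so this comparison decides nothing about the normalised values. The shift was itself small against the list mean of -0.69 over lines. A further explanation, loss of thymocytes, was not tested. The lines were selected for loss of rag1 signal in the thymus, which does not by itself show a loss of cells.

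Calls on the chromosome of the mutated gene were weighed against alleles that differ between mutants and siblings in the linked region. Such alleles predict more calls near the mutated gene, and the odds ratio of neighbours against farther genes was 1.62. An uneven spread of responsive genes predicts the same excess with the calls of other lines, and that odds ratio had a geometric mean of 0.934 over lines (range 0.666 to 1.39). Part of the calls on that chromosome may thus be linked variants of the mixed strains and not responses to the mutation, though reads were not examined. Over all 32 lines the odds ratio was 1.36 (1.28 to 1.44), with 1.45 (1.28 to 1.63) for neighbours.

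In the atad5a table each mutant column matched a wild-type column, with equal counts in 94.7%, 94.3% and 95.01% of genes, where unmatched columns of that table shared at most 0.81%. These shares are of genes with at least 50 reads summed over the 2 libraries compared. One set of libraries under both genotypes predicts such pairs. The authors' deposited table has 0 genes at an adjusted p under 0.05 for this line, and the labels do not settle which genotype the columns have. No biological explanation was tested.

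Single libraries lay far from the others of their group in depth in 7 of 59 groups and in the count of a named gene in 23 of 264 groups, where chance flags about 1 in 20. The depths, in M reads, were 4.48 (foxn1 wild type), 23.4 (tnpo3 wild type), 178 (pi4kaa mutant), 77.5 (upf1 wild type), 5.91 (mcm10 wild type), 12.9 (mcm10 mutant) and 12.3 (jak3 mutant). Gene counts in a wild-type library, in normalised reads, were 0.79 for nlrc11 and 163 for NOS2 in foxn1, 74.7 for nlrc8 and 89.0 for nlrc3l2 in pole1, 0.958 for pimr178 in zbtb17, 80.2 for bmb and 504 for GRIFIN in nol9, and 1596 for MAT2A in mat2aa. Others in a wild type were 1606 for scpp8, 0 for lepa and 74.2 for psmb13a in unc45a, 12.6 for sla2a in cstf3, 36796 for EIF5 in eif5, 94.7 for bfb and 148 for NEU3 in gemin5, and 706 for CPA1 in snapc3. Those in a mutant library were 54.0 for lrrc66 in tnpo3, 694 for cela1.5 in upf1, 106 for ccl34a.4 in mcm10, 92.2 for isg15 in spata5, 316 for UNC45A and 4.50 for gig2l in unc45a, and 661 for FLI1 in fli1a.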

How the results depend on the processing

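No named gene changed its sign to a call in the other direction under any alternative. Among 1384 pairs of a named gene and a line, 16578 refits left 15862 on the same side of the threshold, 642 lost a call (602 with a library left out, 20 with no filter, 17 with edgeR, 2 with TMM factors and 1 with a pseudocount of 5) and 74 gained 1. Counts of calls moved by over 1.5 times with no filter in il7r (1), npas4b (1) and rag1 (9), and with edgeR in tbcb (5), il7r (1) and npas4b (2). Pairs of line and list called were 602 with camera, 0 with an estimated correlation, 169 with fry (163 shared) and 600 with a pseudocount of 5. The preset correlation was 0.01 against a median estimated one of 0.26, and a higher correlation raises the camera p-values. Other contributions to the loss of calls were not tested. Leaving out 1 library moved the count by over 1.5 times for 136 of 255 libraries in 28 lines, 119 below and 17 above. Counts without each library are given as lowest to highest, then those that moved (W wild type, M mutant, with the number of the library in its table): lsm8 467 to 898 (W1 467, W2 547, M5 548, M6 483, M8 536), top3a 0 to 11 (W2 2, M5 11), foxn1 61 to 279 (W1 73, W2 66, W4 117, M5 76, M6 61, M8 97), tnpo3 1106 to 2280 (W3 1211, W4 1299, M6 1107, M7 1106, M8 1176), pi4kaa 7579 to 10543, pole1 557 to 1268 (W1 798, W2 675, W4 632, M5 557, M6 674), tbcb 2 to 4 (W1 4, W2 4, W3 2, M4 2, M5 4, M6 3, M7 2), upf1 1963 to 3503 (W1 2007, W2 1963, M8 2096), zbtb17 125 to 249 (W1 161, W3 160, W4 125, M6 161, M8 162), nol9 8 to 76 (W1 76), il7r 1 to 20 (W1 20, W3 4, W4 1, M5 1, M6 1, M7 9), mat2aa 4476 to 6400, mcm10 16 to 35 (W1 22, W2 24, W3 16, W4 20, M6 19, M7 20), spata5 96 to 296 (W1 219, W2 96, W3 128, W4 189, M5 261, M6 195, M8 211), pip5k1ba 4220 to 5287, ikzf1 28 to 46 (W1 31, W2 29, W4 28, M6 35), unc45a 1266 to 4597 (W2 1266, W3 1345, W4 1389, M5 1705, M8 1818), ube3d 12 to 31 (W3 14, W4 20, M5 22, M6 17, M7 12, M8 25), jak3 4 to 16 (W1 4, M6 16), cmyb 9 to 45 (W1 10, W2 10, W4 9, M5 45), npas4b 0 to 412 (W1 412, W2 1, W3 0, M6 0, M7 0), nek7 995 to 1724 (W2 995), cstf3 3511 to 4839, dnmt1 1 to 4891 (W1 2, W2 1749, W3 3, M6 1), cct5 21 to 209 (W1 209, W3 21, W4 52, M5 21, M6 54, M7 22, M8 37), naa50 7 to 21 (W1 8, W3 21, M7 7), anapc1 0 to 3 (W1 3, W2 0, W3 0, M5 0, M6 0, M7 0, M8 2), fli1a 9 to 103 (W2 9, W3 11, W4 52, M5 51, M6 10, M7 43, M8 47), eif5 2167 to 9077 (W1 3022, W4 9077, M5 2570, M6 2268, M7 2167, M8 2792), gemin5 81 to 1143 (W1 136, W2 81, W3 131, W4 197, M5 171, M6 131, M7 1143, M8 121), snapc3 657 to 1836 (W1 897, W3 657, W4 711, M7 802), rag1 0 to 16 (W1 16, W2 2, W3 9, M4 2, M6 0). The balance of higher and lower calls turned over in 30 of 383 refits, in 14 lines, 25 of them with a library left out. These are given as higher and lower, named as above: tnpo3 (W1 1215 and 1065), pi4kaa (TMM 4721 and 5005), pole1 (W3 532 and 531), tbcb (edgeR 2 and 3), zbtb17 (no filter 145 and 138, W1 81 and 80, W2 94 and 82, W3 86 and 74, W4 66 and 59, M6 81 and 80), nol9 (W1 15 and 61), il7r (W1 15 and 5, W3 3 and 1), pip5k1ba (no filter 2612 and 2478, TMM 2565 and 2534, M11 2125 and 2119), ube3d (M8 11 and 14), jak3 (W1 3 and 1, W4 4 and 3), dnmt1 (W1 0 and 2, W3 1 and 2, M6 0 and 1), cct5 (W3 13 and 8, W4 29 and 23, M5 15 and 6, M7 16 and 6, M8 20 and 17), fli1a (M5 25 and 26, M7 20 and 23), eif5 (W4 4833 and 4244). Without a dnmt1 mutant, the lone other mutant is assumed to vary like the wild types.

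No paired analysis was possible because the columns of the tables carry genotypes and not the replicate numbers of the labels. For the same reason the batch term for pip5k1ba and the extra control for rag1 were not run. The T cell list mean was -0.57 with medians, -0.56 with a pseudocount of 5, -0.68 without the 4 lines on the list, and -0.71 to -0.66 with each line left out, an alternative chosen after the data were seen. Genes called in at least 11 lines numbered 44 with edgeR (43 shared) and 36 with a change of at least 1.5-fold. The difference between lines within and between classes was -0.0148 (p = 0.70), -0.0365 with Spearman (p = 0.94), -0.0170 for genes with a mean of at least 100 (p = 0.72), and -0.0272 with lines of no shared function unclassed (p = 0.84), the last chosen after the data were seen. The odds ratio for the chromosome over all 32 lines with genes of a mean of at least 10 was 1.39 (1.32 to 1.46), and 1.48 (1.32 to 1.66) for neighbours, also chosen after. Depth limits genes near the filter most in libraries of 4.48 and 5.91 M reads.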

Other observations

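Other tissue and stress lists were called by camera in both directions, depending on the line. The proteasome list was called up in 13 lines and down in 9, the unfolded protein response list in 7 and 6, liver in 8 and 10, the circadian clock list in 4 and 11, and cartilage in 7 and 3, none of them with an estimated correlation. In pi4kaa the cartilage list (1 higher, 22 lower of 24, mean -1.60, adjusted p = 7.2e-11, adjusted p = 0.32 with an estimated correlation) was lower and the proteasome list (38 higher, 0 lower of 42, mean 0.87, adjusted p = 1.1e-12, adjusted p = 0.62 with an estimated correlation) higher, as was the endoplasmic reticulum unfolded protein response list (24 higher, 1 lower of 27, mean 0.78, adjusted p = 2.3e-07, adjusted p = 0.58 with an estimated correlation). The chaperone gene HSP90B1 (ENSDARG00000003570) rose in 6 lines and fell in 2, and HSPA5 (ENSDARG00000103846), the main chaperone of the endoplasmic reticulum, rose in 5. Liver genes were lower in nek7, the liver list (0 higher, 16 lower of 26, mean -1.96, adjusted p = 5.4e-21, adjusted p = 0.26 with an estimated correlation), and the cytochrome gene cyp2ad2 (ENSDARG00000021172) fell in 9 lines and rose in 0. The clock list was highest in unc45a, the circadian clock list (7 higher, 0 lower of 33, mean 0.63, adjusted p = 3e-06, adjusted p = 0.63 with an estimated correlation), against its more common direction, and the clock repressor gene BHLHE41 (ENSDARG00000041691) fell in 4 lines.

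The T cell list mean was compared with 6 other measures over 32 lines. Its correlation with the exocrine pancreas list mean was r = 0.43 (permutation p = 0.014, adjusted p = 0.084) and 0.20 without nek7 and anapc1, and none of the 6 passed.

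The genotype split was compared with all other splits of the same libraries into groups of the same sizes, a test chosen after the counts were seen. The number of calls was the highest of 35 splits in 24 lines, given as the real count against the highest other: lsm8 877 against 7, foxn1 186 against 2, tnpo3 2010 against 4, pi4kaa 9755 against 3, pole1 1374 against 18, tbcb 8 against 2, upf1 3328 against 4, zbtb17 261 against 60, nol9 11 against 2, mat2aa 6022 against 2, mcm10 38 against 11, spata5 397 against 163, ikzf1 57 against 13, unc45a 3522 against 3, ube3d 42 against 3, cmyb 21 against 12, nek7 1547 against 9, cstf3 4829 against 2, cct5 83 against 44, naa50 13 against 5, fli1a 82 against 4, eif5 4547 against 2, gemin5 438 against 4, snapc3 1408 against 3. In pip5k1ba it was 5116 against 1111 in 100 drawn splits. In top3a all 35 splits had at least the 0 calls of the real split (highest other 2), in il7r 14 of 35 had at least 2 (12), in jak3 2 of 35 at least 9 (12), in npas4b 6 of 35 at least 4 (7), in anapc1 5 of 35 at least 1 (1732), and in rag1 2 of 10 at least 4 (4). The dnmt1 line, with 2 mutants, was not split. The 1732 calls of another split in anapc1 show that embryos there can differ widely regardless of genotype.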
